A study of Homo sapiens with 6 samples.

How the data were processed

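RNA-seq was done on 6 libraries of 231BR cells, 3 with an empty vector (shEV) and 3 with a hairpin against IL13RA2 (shIL13RA2). Per the labels' protocols, total RNA was isolated with Trizol and a column cleanup, and a sequencing service built the libraries. Per the submitters' processing notes, FastQC, HISAT2 2.1.0, Cufflinks 2.21 and Cuffdiff were used with the build GRCh38.p13; their roles, the annotation release and the strand setting are not given in the sources used here.

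The authors deposited 2 tables with 1 column per library. The deposited count table holds a signal per gene, namely estimated fragment counts divided by 1 size factor per library, not raw counts. This was read from its values: 96.86% to 97.08% of nonzero values were whole multiples of a step per library, from 0.9452 to 1.1138, within 0.02 steps, and the rest were fractions. Totals divided by that step were 15931632 to 18130557. The second deposited table holds FPKM from the same libraries. Columns were assigned to groups by their names; they are numbered 0 to 2 and the sample titles 1 to 3, so no column was matched to a single sample.

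Tables had 60086 rows. The row that names no gene had a count of 0 and was left out. Genes on alternate loci are listed in several rows; 6270 such rows were summed with their gene, leaving 53815 symbols. These rows held 0.263% of the counts, but 594 tested genes in several rows had a median SE of 0.312, against 0.095 for genes in 1 row. ATP6 and ATP8 are listed at 0 in the tables and have no value here. Summing was decided before any test.

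The design fixed before the data were examined named the count test of edgeR, with estimated counts that are not whole rounded first. Since the deposited values are not raw counts, limma 3.58.1 in R 4.3.3 was used instead, with an empirical Bayes trend on log2(normalized count + 1), the authors' scaling and Benjamini-Hochberg adjustment with a threshold of 0.05. Genes with at least 10 normalized counts in at least 3 libraries were tested. Such fold changes understate changes of low genes. Adjusted p in the text is from this limma fit unless camera is named. The 35 gene lists were fixed before the data were examined and tested with limma's camera (preset correlation 0.01; at least 3 tested members, which 34 lists had), with an estimated correlation and with fry beside it. The exact permutation test for 3 against 3 libraries cannot go below 0.1.

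The rule for named genes was fixed before the data were examined. It takes IL13RA2, and the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, at least 5 CPM in the higher group and no overlap between groups, without predicted loci and pseudogenes. It takes up to 4 passing members of each called list, and at most 2 of each other list or, where none passes, the most abundant. It adds 10 genes chosen for the design, and in the closing section the 5 smallest p-values not yet named. This gave 112 genes, of which 1 is not reported here.

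Gene positions came from GENCODE 29 (GRCh38) for 92.5% of tested genes. Shifted stretches were found among 12837 genes listed in 1 row by recursive segmentation of fold changes limited to ±1, with at least 20 genes, 500 permutations per step, a permutation share of at most 0.001 and an absolute median of at least 0.15. The first run gave 7 pieces. Touching pieces of the same sign were then joined, and a piece of 14 genes at the start of chromosome 20 was left out as too short, leaving 4 stretches. The settings were chosen after the shifts had been seen, and the joining and the leaving out after the first run.

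Library pairs were compared over genes averaging at least 100 counts. Pairs within a group differed by more than counting noise (chi-square per gene 4.33 to 23.11), so no library was counted as a copy of another. Pairs between groups gave 19.77 to 47.26, so shIL13RA2 libraries 0 and 2 (23.11) differed as much as some pairs between groups. With simulated libraries of this comparison (14570 genes tested, 200 changed), the limma fit called 61.2% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 95.5% of those changed 4-fold, with 9 unchanged genes called. In a further simulation over 14562 genes camera called the 1 shifted list and 0 of 99 random lists. Genes were drawn independently there, so it does not show how often camera calls lists whose members are correlated. The segmentation, tested on shuffled values of 12837 genes, recovered 100% of the genes of each of 3 simulated stretches, with 9 genes outside. The simulated shifts were all larger in size than the median of -0.19 of the chromosome 20 stretch, so recovery of so small a shift was not tested.

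Alternatives covered the scaling, filters, pseudocount, FPKM values, a block on the column number, each library left out, a 1.5-fold threshold, the set test, the summing of rows, robust empirical Bayes and the genes of the shifted stretches. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.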

Results

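The study used 231BR, a brain-tropic derivative of the MDA-MB-231 human breast cancer cell line, carrying a doxycycline-inducible vector. One cell population held an empty vector (shEV) and the other a hairpin, shRNA-8523, against IL13RA2 (shIL13RA2). Per the labels, each population was seeded into triplicate plates and induced for 96 hr with 1 ug/ml doxycycline. RNA-seq gave 3 libraries per group, 6 in all. The deposited normalized counts summed to 17441056 to 17818154 per shEV library and 16977650 to 17618242 per shIL13RA2 library. Because the plates of a group came from 1 cell population, p-values measure the spread between plates, which may be technical. The libraries are numbered 0, 1 and 2 within a group, as in the deposited tables. Values are mean normalized counts ± SD (n = 3), and log2 fold changes, on the log2(normalized count + 1) scale, are shIL13RA2 relative to shEV with a standard error (SE).

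The single comparison asked how the transcriptome of induced cells with the hairpin differed from that of induced cells with the empty vector. No uninduced library is in the series, so a gene that rose or fell is one higher or lower than in shEV cells. The series title concerns a role of IL13RA2 in the proliferation of brain metastases. IL13RA2, which encodes a high-affinity receptor for interleukin-13, was lower in the shIL13RA2 cells, so the libraries matched their labels. Its normalized counts were 49.01, 80.03 and 80.84 in the shEV libraries and 16.07, 33.78 and 15.55 in the shIL13RA2 libraries. The group means were 70.0 ± 18.1 and 21.8 ± 10.4, leaving 31.2% of the shEV level (log2 fold change -1.69, SE 0.32, adjusted p = 0.00797; 95% interval -2.42 to -0.96). All shIL13RA2 values lay below all shEV values, and the exact permutation test gave its smallest possible two-sided p for 3 against 3 libraries, 0.1. In FPKM the means were 3.22 and 0.998. The gene, ENSG00000123496.7, lies on the minus strand of chromosome X from 115003975 to 115019977 in GRCh38 and is annotated as protein coding with up to 11 exons. Its counts are low, and on log2(FPKM + 1) values without a filter on low genes the adjusted p was 0.0596 (range over all alternatives 0.00242 to 0.0596).

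Other parts of the receptor system moved little. Of 15 tested genes of the IL-13 and IL-4 receptor list, IL13RA2 and IL13RA1 fell and 13 did not pass the test, with the same counts adjusted over the list alone. IL13RA1, the signalling receptor chain for IL-13, fell 1.26-fold from 726 ± 20.7 to 576 ± 32.0 (adjusted p = 0.0107), a call lost without shEV library 0. IL4R, the chain with which IL13RA1 pairs, was at 643 ± 41.8 and 670 ± 92.2 (adjusted p = 0.784). STAT6, the transcription factor that this receptor pair activates, was at 1888 ± 107 and 1677 ± 115 (adjusted p = 0.131). The list was not called by camera (adjusted p = 0.286).

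Across the transcriptome, 2121 of 14481 tested genes passed an adjusted p of 0.05 in limma, 954 higher and 1167 lower in shIL13RA2 cells; under total-count scaling 1088 were higher and 1018 lower. Of the 2121 genes, 311 differed at least 2-fold, 197 of them higher and 114 lower. Values of the groups did not overlap for 35.2% of tested genes, where chance gives 10%. The first principal component, 48.3% of the variance, separated the groups, and the second, 18.4%, spread the shIL13RA2 libraries (scores -25.6, 5.5 and 25.2 for libraries 0, 1 and 2). Leaving out 1 library lowered the count of passing genes by more than 1.5 times in 4 cases: it was 1131, 1354 and 1097 without shEV library 0, 1 and 2, and 1201 without shIL13RA2 library 1.

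The largest rises were mostly in genes of low expression in shEV cells, with 1 abundant protease among them. MMP1, an interstitial collagenase, rose 9.30-fold from 6353 ± 312 to 59076 ± 2128 (log2 fold change 3.22, SE 0.06, adjusted p = 6.18e-09). MMP9, a gelatinase, rose from 4.55 ± 3.59 to 102 ± 8.22 (log2 fold change 4.46). SIRPA, an inhibitory receptor that binds CD47, rose 20.7-fold, and KALRN, a guanine nucleotide exchange factor, rose 14.8-fold. The ephrin receptor EPHB1 rose 9.50-fold, the laminin chain LAMA1 7.23-fold, the cytoskeletal adaptor HCLS1 6.39-fold and the neutrophil chemokine CXCL1 6.28-fold. MAPRE3, a microtubule end-binding protein, rose 6.05-fold and the formin DAAM2 5.96-fold. Adjusted p for these 10 genes was at most 0.00042.

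The largest falls included genes that were nearly silent in shIL13RA2 cells. CCND2, encoding cyclin D2, had 191 ± 19.8 normalized counts in shEV cells and about 1 count in each shIL13RA2 library. Its normalized level was 0.508% of that in shEV cells (95% exact binomial interval 0.104% to 1.49%, from 551 and 3 counts before scaling, counting error only). EEF1A2, an elongation factor isoform, fell 22.6-fold from 941 ± 50.8 to 40.7 ± 1.75. NPR2, the receptor for C-type natriuretic peptide, fell 20.1-fold from 1659 ± 145 to 81.8 ± 9.93. VAT1L fell 15.5-fold, and SEMA3B, a secreted semaphorin, fell 3.61-fold. ALPP, placental alkaline phosphatase, fell as well (log2 fold change -3.46), but it may share reads with a near-identical paralog. CLK2 (adjusted p = 0.00155), TBCE, TMEM14C and UBL7 also met the rule for the 10 largest falls. The deposited tables list each of these 4 genes in 2 rows, so that reads may be split between copies, and their changes are uncertain.

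**Figure D1:**
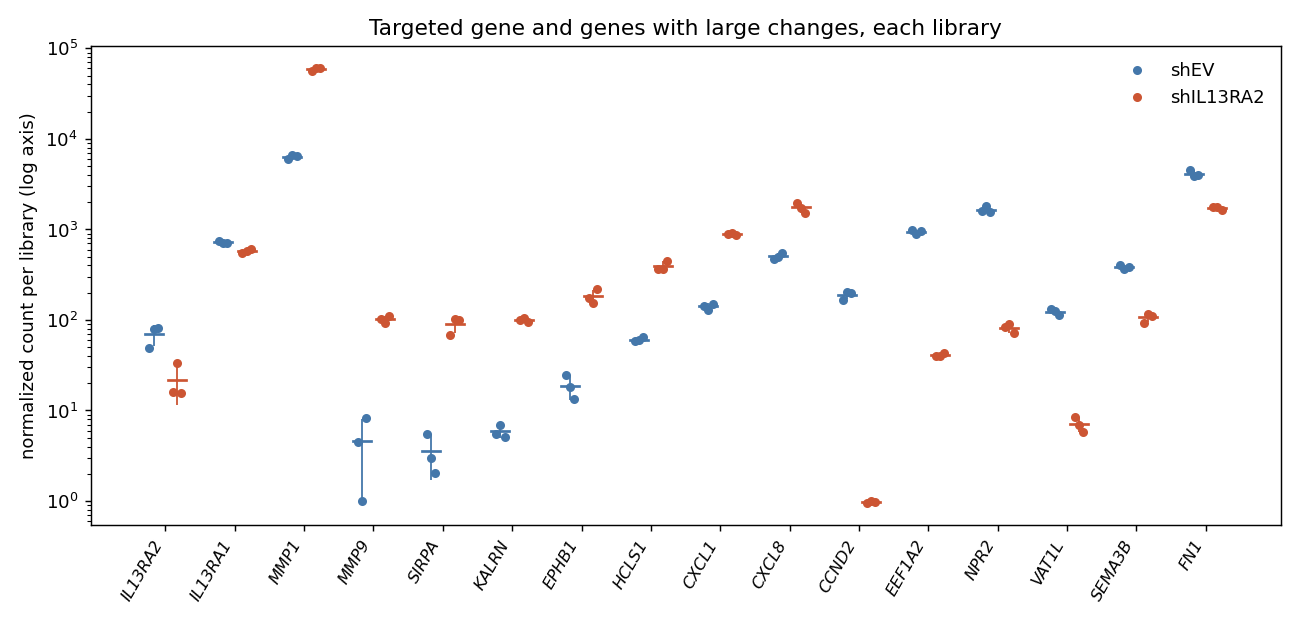
Normalized counts of the targeted gene, IL13RA1 and 14 genes with large changes, on a log axis; each point is 1 library, the bar is the group mean and the line its SD (n = 3). MMP1 rises 9.30-fold and CCND2 stands near 1 count in the shIL13RA2 libraries.

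Genes for cytokines, chemokines and NF-kB targets were higher as a group in shIL13RA2 cells. Of 25 tested members 19 rose, 3 fell and 3 did not pass; adjusted over the list alone 21 rose and 3 fell. The median log2 fold change was 0.84 (camera adjusted p = 2.62e-12; adjusted p = 0.0504 with an estimated correlation). CXCL1 rose as above, CXCL8, another neutrophil chemokine, rose 3.43-fold from 507 ± 38.1 to 1749 ± 226, and IL1A, a proinflammatory cytokine, rose 4.75-fold. IL11, an interleukin-6 family cytokine, went the other way and fell 2.27-fold from 1027 ± 46.7 to 453 ± 39.9.

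**Figure D2:**
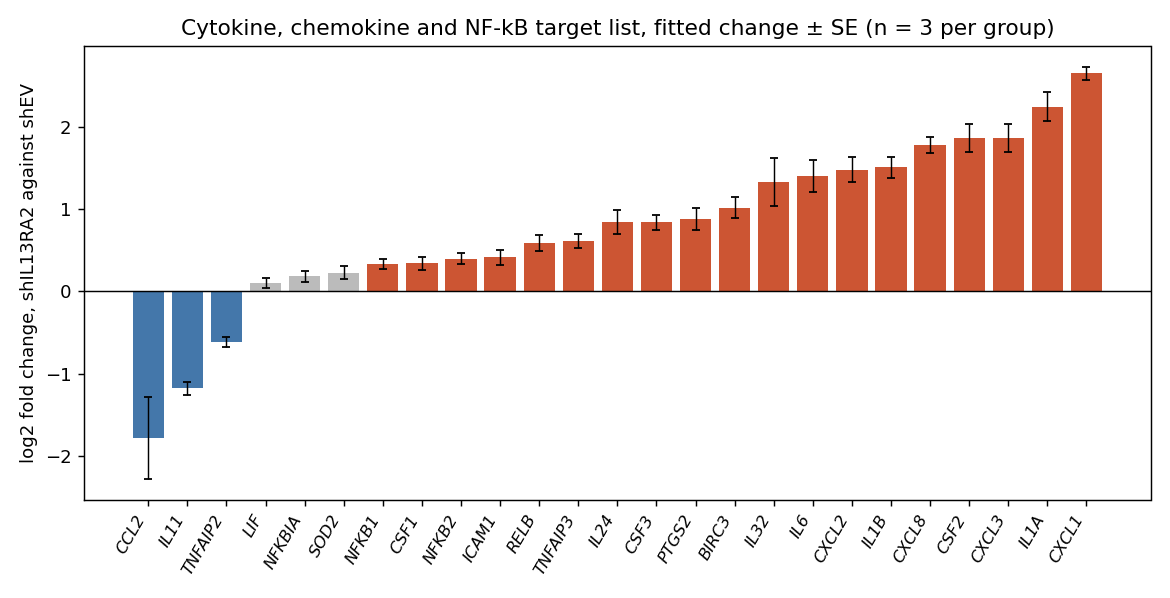
Fitted log2 fold change of each tested gene of the cytokine, chemokine and NF-kB list, with its SE (n = 3 per group); orange and blue bars passed an adjusted p of 0.05 as higher or lower, grey bars did not. CXCL1 and IL1A lead the 19 genes that rose, and IL11 is among the 3 that fell.

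Several other groups were also called higher, all with weaker support when camera estimated the correlation. The estimates were 0.006 for the inflammatory list, -0.028 for interferon-stimulated genes, -0.148 for histones and -0.012 for MHC class I presentation. All lay below the preset 0.01, so for these lists the weaker support is no sign of correlated members. Apoptosis regulators and matrix proteases had 0.014 and 0.018, and the lists called lower 0.108 to 0.796. Among interferon-stimulated genes 8 of 30 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.17; camera adjusted p = 0.00246; adjusted p = 0.207 with an estimated correlation). MX1, an antiviral GTPase, rose 3.20-fold, the oligoadenylate synthetase OAS3 2.07-fold and USP18, which removes ISG15 from proteins, 1.89-fold, while IFI44L fell 2.12-fold. Of 6 tested replication-dependent histones 4 rose, also adjusted over the list alone (median 0.59; camera adjusted p = 0.00237; adjusted p = 0.207 with an estimated correlation). They were HIST1H2BK (1.56-fold), HIST1H1C (1.55-fold), HIST1H2AC (1.90-fold) and HIST1H2BD (1.39-fold). Of 15 genes of MHC class I presentation 3 rose, HLA-B (1.70-fold), HLA-C (1.68-fold) and B2M (1.16-fold); adjusted over the list alone 5 rose and 1 fell. Camera called this list (adjusted p = 0.0300; adjusted p = 0.231 with an estimated correlation), but all 3 genes are listed in several rows. The call was lost without such genes (adjusted p = 0.497), with rows not summed (0.104), without shEV library 1 (0.0894) and without shIL13RA2 library 2 (0.169).

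The lists of apoptosis regulators and of matrix proteases and inhibitors were called higher, although most of their members did not pass. Of 21 apoptosis regulators 7 rose and 1 fell, 8 and 1 adjusted over the list alone (median 0.15; camera adjusted p = 0.00267; adjusted p = 0.222 with an estimated correlation). The inhibitors of apoptosis BIRC3 and BIRC2 rose 2.03-fold and 1.51-fold, and both lie in a stretch of chromosome 11 described below whose genes were mostly higher. BCL2A1, another survival gene, rose 1.66-fold, and TNFRSF10B, a death receptor, 1.29-fold. Of 21 extracellular matrix proteases and inhibitors 9 rose and 1 fell; adjusted over the list alone 9 rose and 3 fell. This list had a median of 0.07 (camera adjusted p = 0.0107; adjusted p = 0.231 with an estimated correlation) and was not called without shIL13RA2 library 2 (0.101). Beside MMP1 they included the lysosomal protease CTSL (1.84-fold), ADAMTS1 (1.63-fold) and the urokinase gene PLAU (1.43-fold).

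Lists called lower were matrix proteins, luminal breast markers, and glycolysis and hypoxia genes, each with members that did not pass. Of 23 collagens, laminins and other matrix proteins 8 fell and 4 rose, 9 and 4 adjusted over the list alone (median -0.16; camera adjusted p = 0.0338; adjusted p = 0.478 with an estimated correlation). FN1, fibronectin, fell 2.39-fold from 4126 ± 321 to 1723 ± 81.7, LAMA5 1.76-fold, COL8A1 1.68-fold and TNC, tenascin C, 1.56-fold. The call was lost without shEV library 0 (0.144), shEV library 1 (0.0894) or shIL13RA2 library 2 (0.0795). Of 9 tested luminal breast markers 5 fell, also adjusted over the list alone (median -0.32; camera adjusted p = 0.00237; adjusted p = 0.231 with an estimated correlation). The keratins KRT19 and KRT8 fell 1.88-fold and 1.61-fold, AGR2 1.78-fold and the transcription factor SPDEF 1.96-fold. Of 29 glycolysis and hypoxia genes 11 fell and 1 rose, 13 and 2 adjusted over the list alone (median -0.18; camera adjusted p = 0.00807; adjusted p = 0.478 with an estimated correlation). GAPDH fell 1.70-fold, TPI1 1.41-fold and PFKFB4 1.72-fold, while the glucose transporter SLC2A1 rose 1.36-fold. GAPDH and TPI1 lie in a stretch of chromosome 12 whose genes were mostly lower. With the genes of all such stretches left out the list stayed called (0.0354) at a median of -0.16 (SD of members 0.29, against 0.30 with them). With the stretch medians subtracted it was not called (0.0741) at a median of -0.14 (SD 0.29).

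Mitochondrially encoded messenger RNAs were called lower as a group by camera but not by fry (adjusted p = 0.198), with 1 of 10 passing, ND4L (1.28-fold lower, adjusted p = 0.0458). Adjusted over the list alone 7 were lower and 1 higher (median -0.35; camera adjusted p = 0.0168; adjusted p = 0.478 with an estimated correlation, which was 0.796 against the preset 0.01). They made up 2.84% to 3.46% of the counts in shEV libraries and 1.92%, 2.76% and 2.68% in shIL13RA2 libraries 0, 1 and 2.

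The cell cycle lists, to which the series title points, were not called by camera, while fry called DNA replication lower (adjusted p = 0.0376) and not mitosis (0.0888). Of 42 mitosis and G2/M genes 6 fell and 2 rose, 7 and 2 adjusted over the list alone (median -0.03; camera adjusted p = 0.237). Of 47 DNA replication genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone (median -0.03 at this scaling and 0.003 under total-count scaling; camera adjusted p = 0.234). The proliferation marker MKI67 was at 7080 ± 105 and 6483 ± 373 (adjusted p = 0.161). CCNA2, encoding cyclin A2, fell 1.24-fold and the thymidine kinase TK1 and the replication factor GINS4 each fell 1.24-fold. DLGAP5, a mitotic spindle gene, fell 1.36-fold; it lies in the chromosome 14 stretch described below, and its change was 0.07 after the stretch median was subtracted. CCND1, cyclin D1, fell 1.14-fold (adjusted p = 0.0374) and MYC rose (log2 fold change 0.32, adjusted p = 0.0392). The MYC call was lost without shEV library 0, 1 or 2 or shIL13RA2 library 1 or 2, and the CCND1 call without shEV library 0, 1 or 2 or shIL13RA2 library 1. Among growth arrest genes 2 of 17 rose and 2 fell, 4 and 3 adjusted over the list alone (camera adjusted p = 0.982). TXNIP rose 1.44-fold, and the CDK inhibitor CDKN1B, in the chromosome 12 stretch, fell 1.70-fold. CDKN1A, encoding the CDK inhibitor p21, was at 630 ± 42.8 and 772 ± 78.2 (adjusted p = 0.0547). Of 19 p53 targets 3 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 0.366), with GDF15 up 1.88-fold and TP53I3 down 1.45-fold.

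Signalling and stress lists were not called by camera. Of these, fry called the YAP and TAZ and the unfolded protein lists higher (adjusted p = 0.000368 and 0.00794) and the receptor tyrosine kinase list lower (0.0435). Of 26 immediate early and MAPK feedback genes 7 rose and 4 fell, 10 and 4 adjusted over the list alone (camera adjusted p = 0.253). EGR1 rose 1.38-fold (adjusted p = 0.0134, lost without shEV library 0 or 1), ATF3 1.60-fold and IER3 1.58-fold, the last listed in 6 rows. Of 29 receptor tyrosine kinases and ligands 5 fell and none rose, 7 adjusted over the list alone (camera adjusted p = 0.174). TGFA fell 1.56-fold and AXL 1.26-fold, while EGFR was at 13349 ± 109 and 12519 ± 498 (adjusted p = 0.263). Of 30 genes of the unfolded protein and ATF4 response 7 rose and 4 fell, 10 and 4 adjusted over the list alone (camera adjusted p = 0.0924). The chaperone HSPA5 rose 1.38-fold and the pseudokinase TRIB3 fell 1.57-fold. Of 14 heat shock genes 1 rose (DNAJA1, 1.17-fold) and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.273). HSP90AA1, in the chromosome 14 stretch, fell 1.28-fold, and its change was 0.16 after the stretch median was subtracted. Of 18 TGF-beta targets 4 rose and 2 fell (camera adjusted p = 0.366), and of 21 YAP and TAZ targets 6 rose and 3 fell (0.0924). Adjusted over each list alone these were 4 and 2, and 7 and 3. CCN2 rose 1.24-fold, SMAD3 1.22-fold, ANKRD1 1.47-fold and CCN1 1.35-fold.

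Adhesion, migration, lipid, respiratory chain and ribosomal lists were likewise not called by camera. Of these, fry called the brain metastasis and respiratory chain lists higher (adjusted p = 0.000588 and 0.0376) and the integrin, mesenchymal and epithelial lists lower (0.0376, 0.0328 and 0.0433). Of 18 genes associated with brain metastasis 6 rose and 5 fell, 7 and 5 adjusted over the list alone (camera adjusted p = 0.366). Their median log2 fold change was -0.003 and their mean 0.21, so the fry call does not describe most members. MMP1 (log2 fold change 3.22) is a member, and the chemokine receptor CXCR4 rose 2.95-fold. Of 12 integrins 4 fell, ITGB4 2.26-fold and ITGB5 1.40-fold among them; adjusted over the list alone 4 fell and 1 rose (camera adjusted p = 0.253). Of 17 mesenchymal genes 4 fell, PRRX1 1.62-fold, and of 13 epithelial genes 4 fell and 1 rose (camera adjusted p = 0.307 and 0.0892). Adjusted over each list alone, 5 fell and 1 rose in both. Of 26 axon guidance genes 5 rose and 5 fell, 8 and 7 adjusted over the list alone (camera adjusted p = 0.982), with EFNB1 up 2.81-fold and CDH4, listed in 2 rows, down 1.78-fold. Of 17 genes of the lipoprotein receptor and reelin list 2 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.433). RELN, the secreted ligand reelin, rose 3.19-fold from 88.1 ± 20.3 to 281 ± 38.5. VLDLR, a reelin receptor, was at 132 ± 9.88 and 108 ± 13.3 (adjusted p = 0.184). Of 22 cholesterol synthesis genes 1 rose (SC5D, 1.54-fold, in the chromosome 11 stretch) and 1 fell (TM7SF2, 1.79-fold), the same adjusted over the list alone (camera adjusted p = 0.139). Of 19 fatty acid genes 3 rose and 4 fell, 3 and 5 adjusted over the list alone (camera adjusted p = 0.253), with ACSL1 up by 0.32 on the log2 scale and ACSS2 down 1.71-fold. Of 33 nuclear respiratory chain genes 2 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0924). NDUFB8 rose 2.03-fold. NDUFA9, in the chromosome 12 stretch, fell (log2 fold change -0.32), and its change was 0.15 after the stretch median was subtracted. Of 37 ribosomal proteins 2 fell, RPS27 1.21-fold and RPS2 1.20-fold, and 1 adjusted over the list alone (camera adjusted p = 0.0771).

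**Figure D3:**
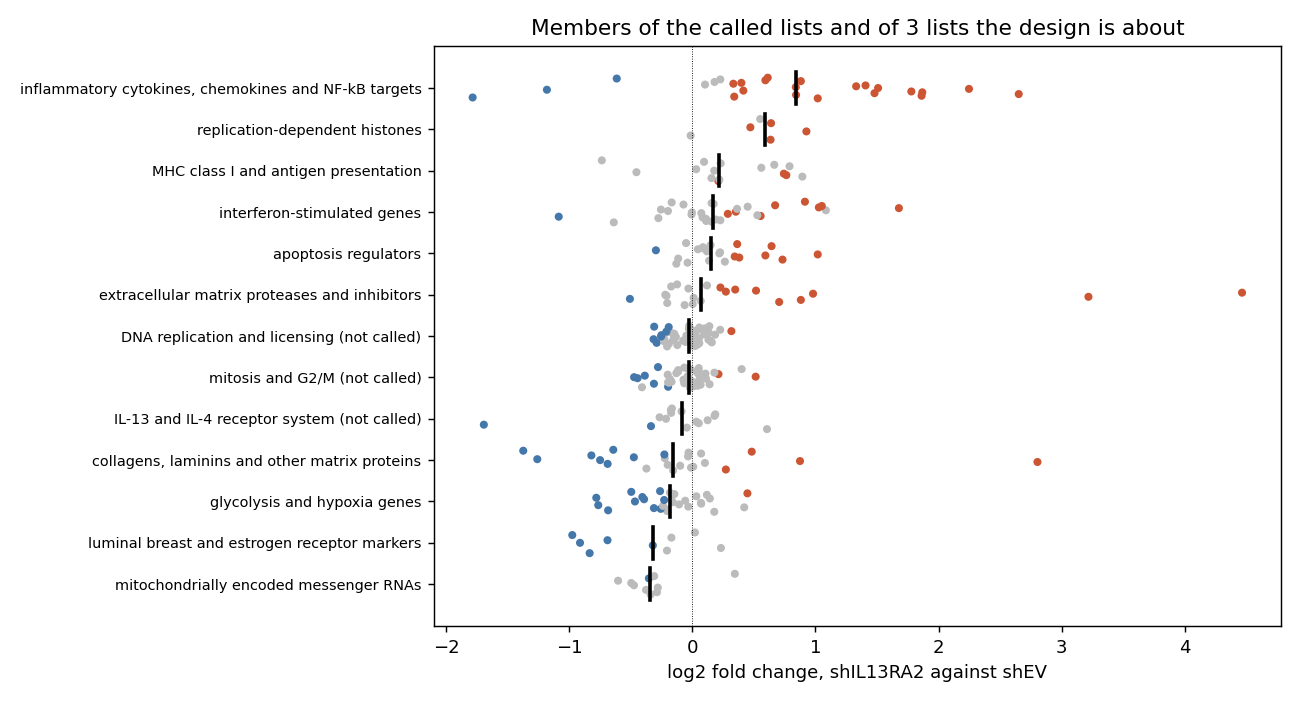
Log2 fold change of each tested member of the 10 called lists and of 3 lists the design is about; points are genes, orange and blue ones passed an adjusted p of 0.05, and black bars are list medians. The inflammatory list has the highest median, 0.84, and the mitochondrial list the lowest, -0.35.

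Of 12 blood and immune markers 10 averaged under 10 normalized counts in both groups; CD14 rose from 4.87 ± 1.13 to 13.3 ± 3.68 and CD68 fell 1.70-fold, the same adjusted over the list alone. Of 5 tested fibroblast and pericyte markers none passed in limma or adjusted over the list alone (camera adjusted p = 0.346), and ACTA2 was at 90.5 ± 13.4 and 116 ± 7.09 (adjusted p = 0.129). Of 5 tested endothelial markers 3 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0522; fry, higher, 0.0247). TIE1, an endothelial receptor that these cells expressed in both groups, rose 1.76-fold from 2368 ± 22.3 to 4175 ± 248, and KDR 1.90-fold. Of 7 neural and glial markers RBFOX3 rose 2.15-fold; adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.850).

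Fold changes were also ordered along the chromosomes. In 4 stretches of neighbouring genes most of the genes were shifted in one direction. On chromosome 14 from 53949736 to 105499575 the median log2 fold change of 257 genes was -0.52 and 94.2% of them were lower. On chromosome 12 from 280129 to 14778002 it was -0.47 over 90 genes, 91.1% of them lower. On chromosome 11 from 102110461 to 134378341 it was 0.35 over 152 genes, 92.1% of them higher; this stretch joins pieces of 21, 129 and 2 genes with medians 0.59, 0.32 and 1.63 above that of all genes. On chromosome 20 from 33407955 to 64079988 it was -0.19 over 224 genes, 80.8% of them lower. Of 747 tested genes inside the stretches 56.8% passed the test, against 12.4% of 13734 others. The stretches were picked by these same fold changes, so a higher share inside and a shared direction follow in part from that choice. CCND2 lies in the chromosome 12 stretch, MMP1 in that of chromosome 11, and MMP9, EEF1A2, LAMA5, ACSS2 and CDH4 in that of chromosome 20. MMP9 rose where its neighbours were lower. With the genes of the stretches left out, an alternative chosen after seeing the data, 1498 of 13734 genes passed, 744 higher and 754 lower. The matrix protease list was then not called (camera adjusted p = 0.0880), with a median of 0.01 (SD of members 0.33) against 0.07 (SD 1.19). Nor was the matrix protein list (0.0578), with a median of -0.13 (SD 0.82) against -0.16 (SD 0.82). The genes left out include the proteases MMP1 and MMP9 (log2 fold changes 3.22 and 4.46), far above the mean of 0.49 of the full protease list. With the stretch medians subtracted, also chosen after seeing the data, both lists stayed called (0.0122 and 0.0177). That subtraction changed MMP1 and MMP9 little.

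**Figure D4:**
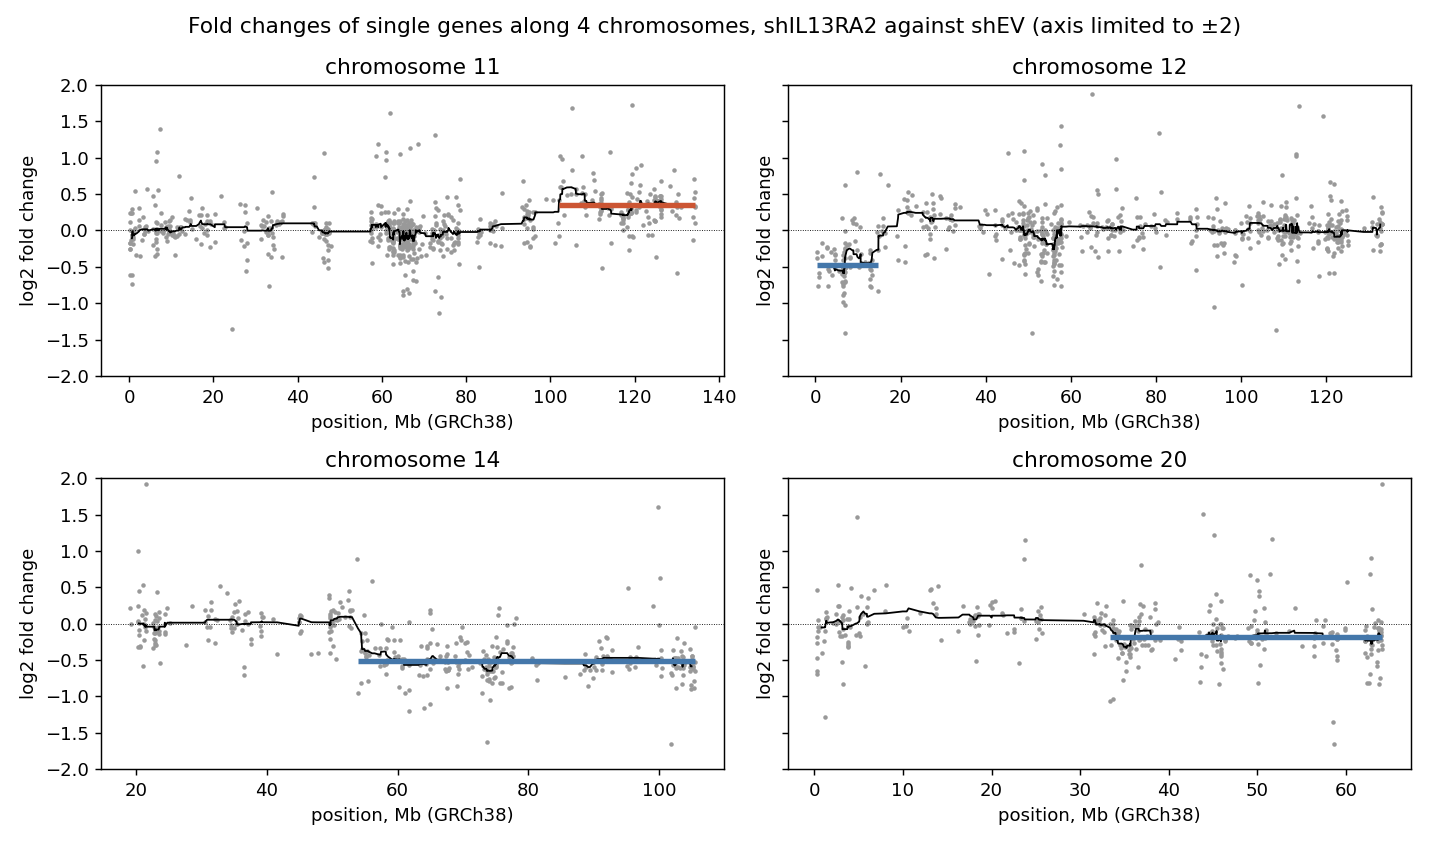
Log2 fold change of each tested gene (grey points, those beyond 2 in either direction not drawn) along chromosomes 11, 12, 14 and 20 in GRCh38 megabases, with a running median (black) and the median of each shifted stretch (thick line). The called stretches begin near 53.9 Mb on chromosome 14 and 102.1 Mb on chromosome 11, edges set by the segmentation.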

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

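The changes of pseudocount, row summing, empirical Bayes and chromosome stretches were chosen after seeing the data. The count of 2121 genes stayed within 1.5 times under the other scalings and filters on counts and on FPKM of at least 1, but was 1119 with log2(FPKM + 1) and no filter, where 26229 genes were tested, and 118 (83 higher, 35 lower) when limma's treat tested against a 1.5-fold change. With each library left out it ranged from 1097 to 2467, with fewer samples in every fit. IL13RA2 stayed lower throughout; its log2 fold change was -1.08 with log2(FPKM + 1) and no filter, where it missed the threshold (adjusted p = 0.0596, range over all alternatives 0.00242 to 0.0596), and -2.04 to -1.51 with each library left out. At a mean count of at least 50 it was not tested. Of 34 tested lists 10 were called, 0 with an estimated correlation and 19 by fry, which tests another question and kept 9 of the 10, losing the mitochondrially encoded list; left-out libraries gave 7 to 13, some of them other lists, and leaving out members shared between lists gave 7 (5 higher, 2 lower). The DNA replication median turned to 0.003 under total-count scaling and was -0.05 to -0.008 with each library left out; the mitosis median was -0.084 to 0.000 there. The causes were not tested.

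Of 112 named genes 105 passed, and 77 of them did so under every alternative that tested them. Leaving out a library ended the call of 14, namely IL13RA1, GINS4, NDUFA9, ND4L, RPS2, HIST1H2BD, B2M, DNAJA1, AXL, CD14, EGR1, CCND1, MYC and PRRX1. IL4R, which never passed, turned to -0.03 without shIL13RA2 library 2 and to 0.00 without shEV library 1, and was at most 0.17 (without shIL13RA2 library 0). After the stretch medians were subtracted DLGAP5 turned to 0.07, HSP90AA1 to 0.16 and NDUFA9 to 0.15 by construction. Another 7 named genes no longer passed, GAPDH, TPI1, SC5D and BIRC2 among them.

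The column numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.113, -0.013 and 0.020, and not every library correlated best with its own number. With the replicate block on the column number 1620 genes passed, 699 higher and 921 lower, and 10 lists were called. edgeR, DESeq2 and limma-voom were not run, since the deposited values are scaled, and the 1.5-fold test used limma in place of edgeR. Counts before scaling could have been approximated from the step of each library, as for CCND2, but count tests on them were not tried. In simulated libraries 61.2% of genes changed 1.5-fold were called.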

Other observations

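The tests of the chromosome stretches, the positions of inflammatory genes, immune cells, the interferon list and 3' UTR matches were chosen only after the result was seen. The 5 genes with the smallest p-values not named so far were of mixed function. SIGLEC15, a sialic acid-binding immune receptor, rose 4.27-fold from 318 ± 22.3 to 1359 ± 20.6, MAGEB2, a cancer-testis antigen, 4.54-fold, ADAMTS6, a secreted protease, 2.99-fold, and PTPRF, a receptor phosphatase, 2.37-fold. HIF1A, the oxygen-regulated transcription factor, fell 2.30-fold from 5049 ± 195 to 2190 ± 62.4 (log2 fold change -1.20), further than the -0.52 of the chromosome 14 stretch in which it lies.

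A comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split gave 2121 genes and 10 lists, and 1 of the 10 splits, the real one, reached each of these counts. The highest of the other splits gave 1 gene and 5 lists.

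The 4 shifted stretches may reflect a difference in DNA copy number between the cell populations, a hypothesis found and tested on the same data. Under it the spread within a stretch stays near that of other genes. The interquartile range was at most 1.115 times that of genes outside (0.265), where large changes of a subset of genes would widen it. Stretches were kept only if their median was shifted, so regulation of a minority of genes could hardly have appeared as a stretch. On chromosome 20 the median of -0.19 is smaller in size than that range, so small changes of a subset would widen it little. The spread therefore cannot tell a copy number difference from modest regulation of many genes. A single aberrant library is argued against, since each shIL13RA2 library reached at least 0.818 of the median shift in every stretch. The chance order of genes is argued against too, since 0 of 20 shuffled orders gave a stretch. The segmentation itself accepts a stretch only against shuffled genes, so these orders are not a separate test. The chromosome 11 stretch was not 1 uniform shift, since it joins pieces with medians 0.59, 0.32 and 1.63 above that of all genes. DNA was not analysed here, and regional regulation by the hairpin stays open as untested, because each group is 1 cell population.

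Position in the stretches is argued against as the cause of the higher inflammatory list by where its members lie. Only 2 of 25 tested members are inside, 1 higher and 1 lower. That 18 of the 19 members that rose lie outside follows almost wholly from this. Effects of genes in the stretches on genes elsewhere were not tested. Immune cells in the cultures are argued against by PTPRC and LYZ, which together averaged 1.60 normalized counts in shIL13RA2 libraries and 4.86 in shEV libraries. These markers were picked from the list of 12 blood and immune markers, of which 10 averaged under 10 in both groups. CD14, another of them, rose from 4.87 to 13.3, and CD68 fell from 2232 to 1318. An interferon response to the hairpin cannot be told apart from other causes, because the interferon-stimulated list had a median of 0.166 with 21 of 30 members above 0 and an SD of 0.547. An effect of lower IL13RA2 and a lasting difference between the cell populations both stay open, since 1 hairpin and 1 control population were compared.

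Hairpins can lower unintended genes through matches of their first bases in 3' UTRs, and the hairpin sequence was not used here. Over 15644 heptamers in the 3' UTRs of 9927 genes outside the stretches, the lowest z was -4.76 and the highest 4.42, so that no heptamer stood out on the lower side. In shuffled values, lowering the genes of 1 heptamer by 0.1 on the log2 scale gave a z of -10.2 or lower in 10 of 10 draws. These draws used only heptamers held by many genes. The scan took heptamers held by as few as 100 genes, where power was not shown. A broad shift of that size from matches to a common heptamer is argued against as the cause of the lower genes outside the stretches. Matches to a rarer heptamer or to few genes stay open.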
